A study of Glycine max with 6 samples.

How the data were processed

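Polyadenylated RNA was sequenced from leaves of the soybean (Glycine max) cultivar HN95 under saline-alkaline stress, in 3 control libraries and 3 libraries from plants sprayed with mesoporous silica nanoparticles (MSN). Per the labels' protocols, plants grew in pots of 20 kg of mixed soil with 3 L of a solution of 40 mM sodium chloride, 40 mM sodium carbonate, 320 mM sodium bicarbonate and 320 mM sodium sulfate, and messenger RNA was enriched with oligo(dT) beads from 1 μg of total RNA and broken into pieces of about 200 bp. Groups and replicate numbers were taken from the sample titles. The labels give 1 batch value and 1 genotype value for all 6 libraries, so neither could be tested against the groups.

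The deposited table holds, per the file headers, a whole-number count and an FPKM value (fragments scaled by gene length and library total) for each of 45967 genes in each library. The authors' FPKM values were normalised by gene length and library total before deposit, and the deposited counts were not normalised. DESeq2 1.34.0 and R 4.1.2 are named in the submitters' processing notes, with no role. The aligner, the counting program, strand setting, genome build and annotation release are not given in the sources used here. Gene identifiers and coordinates are printed as the table gives them, on 20 chromosomes. The table pairs few identifiers with names: 44879 genes had no description of their own beyond "hypothetical protein". Genes were therefore described by the names of the Gene Ontology (GO) and KEGG terms that the table assigns to them. A reference gene table held none of these identifiers and was not used.

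Library totals ran from 63981150 to 67923813 counts. These totals overstate the precision. Among counts from 1 to 12, the value 4 took 17.7 to 19.0% in each library and the value 8 took 10.0 to 12.3%. The values 2, 3 and 5 took 4.92 to 6.70%, 8.27 to 9.42% and 8.17 to 9.15%. Counts thus pile up at 4 and 8, and 1 counting event was taken as 4 counts. Most small counts were not multiples of 4, so this is an assumption. The floors, intervals and counting noise given here rest on it. A count of 0 over the 3 libraries of a group was taken to allow 3 events, or 12 counts, which is 0.0602 CPM (counts per 1000000) in control and 0.0610 CPM in MSN. Folds against a group at 0 are lower bounds set at that floor. Where a group held 1 to 12 counts, an exact binomial 95% interval of the ratio was computed on events of 4 counts. These floors and intervals cover counting error only. Within groups, the median coefficient of variation over replicates was 27.7% in control for genes of 10 to 100 counts, 9.28% for 100 to 1000 counts, 4.43% for 1000 to 5000 counts and 2.91% above 5000 counts. Pairs of libraries within a group differed by 5.48 to 8.03 times the spread of independent single counts, where events of 4 counts alone give 4 times, and shared 0.764 to 0.931% of counts exactly. No pair was a copy of the same values, but repeat runs of 1 library are not excluded by this. Titles call the replicates biological, and whether they came from separate plants or pots is not given in the sources used here, so p-values measure only the spread between these libraries.

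Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with glmQLFit and glmQLFTest, TMM scaling, filterByExpr), 2-sided, with Benjamini-Hochberg adjustment over the 39203 genes tested, a threshold of 0.05 and no fold threshold. This is the form for counts that the design fixed before the data were examined. TMM factors ran from 0.992 to 1.01. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled means ± SD over 3 libraries. The common biological coefficient of variation was 0.0867.

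Lists of genes were fixed before the data were examined, as 39 text patterns. Because descriptions were so sparse, the patterns were also matched to GO and KEGG term names, and texts that matched for another reason were removed before any group was tested. WRKY factors, NAC factors, aquaporins and silicon transport, circadian clock and seed storage markers had no tested gene, and MYB factors and cytosolic ribosomal proteins had 1 each (the MYB gene was higher in MSN and the ribosomal protein gene did not pass), which leaves 32 lists with at least 5 tested genes. After the annotation was seen and before any test, 16 further lists were added from exact term names. Each family of lists was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over its own lists. Camera with an estimated correlation and fry were alternatives. Terms with 10 to 500 tested genes were tested for over-representation by a 1-sided Fisher's exact test, with the 32948 tested genes that carry any term as background and higher and lower genes apart, adjusted over 2033 terms.

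Genes were named by a rule fixed before the data were examined: the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, with at least 1 CPM in the higher group and a description, and the 2 called members with the smallest adjusted p of each of the 9 lists with the most called genes, marker lists apart. It gave 30 genes. Further examples, the called members of highest abundance in the lists past the set test, were chosen after their values were seen. Soybean carries many near-identical gene copies, and how reads shared between copies were counted is not given, so single members of gene families are uncertain.

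The procedure was tested on simulated counts for 39203 genes with the means, dispersions and library sizes of the MSN against control comparison and 200 changed genes. With counts in steps of 4, all of the 50 genes changed 4-fold were recovered (100%), 84.0% of those changed 2-fold, 80.0% of those changed 1.5-fold and 42.0% of those changed 1.25-fold, with 11 false calls. None of 32 random lists (0) passed the set test. The simulated genes varied independently of each other, so lists whose genes vary together were not tested by this. The simulation changed 200 genes, where the data gave 23256 past the threshold. Recovery, false calls and TMM scaling with that many changed genes were therefore not tested. Alternatives were the replicate number as a block, other filters, DESeq2 1.42.0, DESeq2 size factors, quantile normalisation, array weights, the FPKM values on a log2 scale with pseudocounts of 0.1 and 5, a fold threshold, each replicate left out, and, added after the data were seen, FPKM with a pseudocount of 1, counts divided by 4, a test against a fold of 1.5 and the lists as first written.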

Results

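Leaves of HN95, a soybean cultivar, were compared between stressed control plants (3 libraries) and stressed plants whose leaves had been sprayed with mesoporous silica nanoparticles (MSN, porous silicon dioxide particles; 3 libraries). The stress was a saline-alkaline solution added to the soil. RNA was measured 7 days after a spray of 20 mg/L. The treatment tag reads 20, 21 and 22 mg/L on the MSN libraries, and these were kept as 1 group because the titles name 1 treated group and the protocol names 20 mg/L. What the control leaves were sprayed with, if anything, is not given in the sources used here. Control libraries held 65537749, 67795796 and 66059433 counts and MSN libraries held 64796004, 67923813 and 63981150. Ribosomal RNA took 0.223% of the counts in control replicate 2 and 0.0934 to 0.126% in the other libraries. The series title points to photosynthetic carbon metabolism and resistance to salt and alkali as the question.

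MSN leaves differed from control leaves in a large share of the transcriptome. Of 39203 genes tested, 11594 were higher in MSN and 11662 were lower (edgeR quasi-likelihood test, adjusted p threshold 0.05). Most changes were small: the median size of the log2 fold change among called genes was 0.58, and 3636 genes rose and 2748 fell by at least 1 on the log2 scale. The 3 MSN values lay apart from the 3 control values in 65.0% of tested genes, where chance gives 10%. Library profiles correlated at 0.974 to 0.976 within groups and 0.943 to 0.944 between groups, over genes, which are not independent replicates.

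Genes of the photosynthetic apparatus rose together. Of 214 tested genes for photosystems and light harvesting, 172 were higher in MSN, 12 were lower and 30 did not pass, with a median log2 fold change of 0.60. Adjusted over the list alone, the counts were 174 and 12. The set test gave an adjusted p of 2.06e-28, and adjusted p = 0.0652 with an estimated correlation. GLYMA_08G304200, annotated to the oxygen evolving complex that splits water at photosystem II, rose from 173 ± 0.530 to 498 ± 23.2 CPM (SD, n = 3; log2 fold change 1.52, SE 0.04, edgeR adjusted p = 1.52e-16). GLYMA_16G165200, a light harvesting gene, rose from 20.5 ± 0.654 to 76.8 ± 1.60 CPM. They lie on chromosome 8 at 42259456 to 42262441 and on chromosome 16 at 32442602 to 32444100. Among the most abundant members, chosen after their values were seen, GLYMA_05G022900 (photosystem I reaction centre subunit III) rose by 0.51 and GLYMA_10G249000 (photosystem I reaction centre) by 0.43 on the log2 scale, and GLYMA_16G127300 (ferredoxin-NADP+ reductase) by 0.23. In the KEGG antenna protein pathway, 20 of 23 genes were higher and 2 lower (set test adjusted p = 4.68e-09, adjusted p = 0.350 with an estimated correlation). Phloem and vein markers moved the same way in these libraries, with 21 of 37 higher and 2 lower.

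Chlorophyll synthesis and carbon fixation also rose. For chlorophyll synthesis, 43 of 58 genes were higher and 9 lower (set test adjusted p = 3.95e-07; adjusted p = 0.192 with an estimated correlation). Its abundant members, chosen after their values were seen, included a protochlorophyllide reductase gene, GLYMA_12G222200, at 258 ± 5.10 CPM in control and 430 ± 14.5 CPM in MSN. For the Calvin cycle, which fixes carbon dioxide, 27 of 45 genes were higher and 7 lower (median 0.52; set test adjusted p = 3.89e-05; adjusted p = 0.192 with an estimated correlation). Adjusted over the list alone, 43 chlorophyll synthesis and 28 Calvin cycle genes were higher and 10 and 7 lower. Genes annotated with ribulose-bisphosphate carboxylase activity, the carbon-fixing step of Rubisco, took 0.971 to 1.02% of all counts in control libraries and 2.21 to 2.30% in MSN libraries. GLYMA_19G046800 rose from 4602 ± 199 to 9976 ± 272 CPM, GLYMA_19G046600 from 3294 ± 89.1 to 7053 ± 146 CPM and GLYMA_13G046200 from 2034 ± 54.7 to 5557 ± 145 CPM (SD, n = 3). These genes were chosen after their values were seen, and their log2 fold changes were 1.12 (SE 0.03), 1.10 (SE 0.02) and 1.45 (SE 0.03). GLYMA_19G046800 lies on chromosome 19 at 7253610 to 7254976 and GLYMA_19G046600 at 7189031 to 7190508, and GLYMA_13G046200 lies on chromosome 13 at 14043433 to 14044927. How reads shared between these close copies were counted is not given. Under quantile normalisation, which gives equal ranks equal values, both chromosome 19 genes came out at 0 on the log2 scale.

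**Figure D1:**
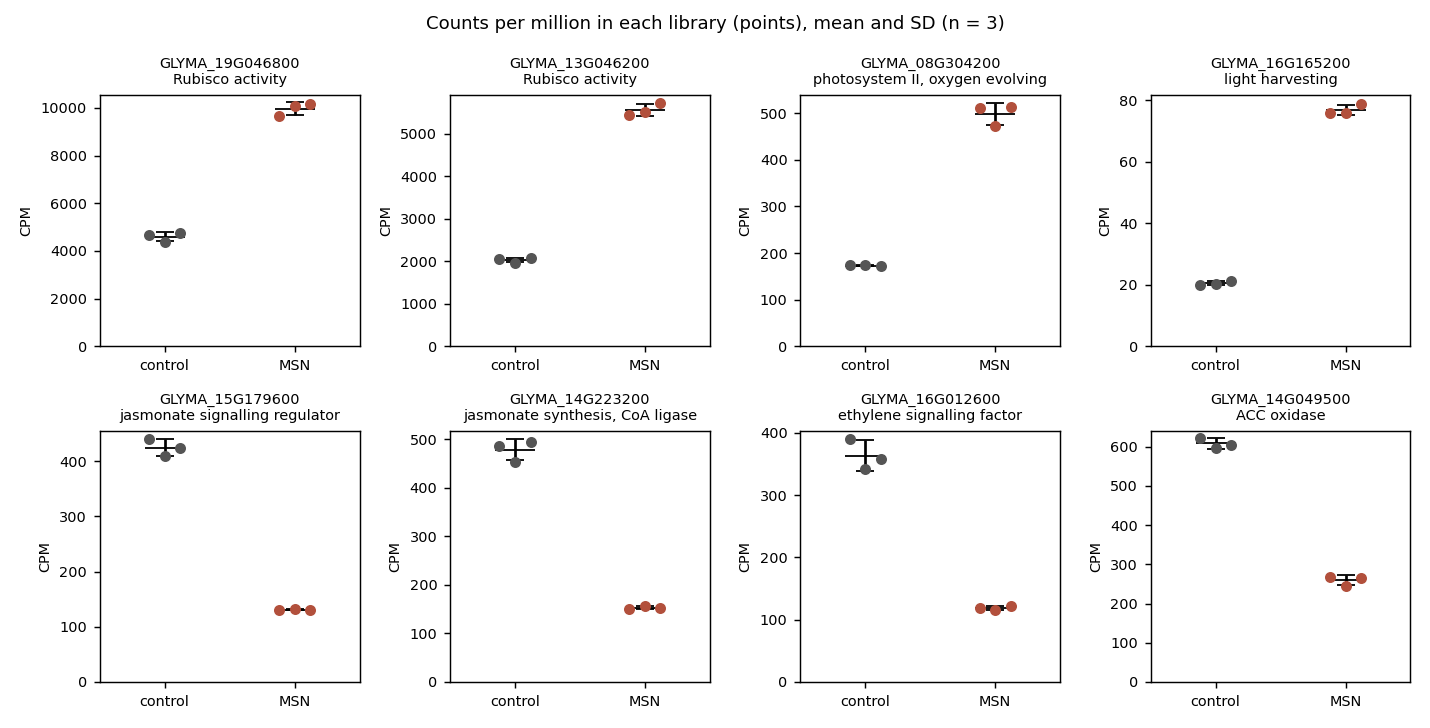
CPM, counts scaled to library size (vertical axes, from 0), in each of the 3 control and 3 MSN libraries for 8 genes, with points for libraries, horizontal marks for the mean and bars for the SD. The photosynthesis genes of the upper row were higher in MSN, such as GLYMA_13G046200 at 5557 against 2034 CPM, and the hormone genes of the lower row were lower, such as GLYMA_15G179600 at 131 against 424 CPM.

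Photorespiration, the recycling of Rubisco's oxygenation product, had 19 of 36 genes higher and 7 lower (set test adjusted p = 3.89e-05, adjusted p = 0.207 with an estimated correlation). Its adjusted p was 0.0696 under quantile normalisation and 0.0650 with array weights, in a range over alternatives of 2.68e-08 to 0.207. GLYMA_15G250800, a hydroxy-acid oxidase gene chosen after its values were seen, rose from 496 ± 17.6 to 823 ± 14.8 CPM. The KEGG carbon fixation pathway had 43 of 78 genes higher and 21 lower (set test adjusted p = 5.73e-05), with adjusted p = 0.350 with an estimated correlation. Its adjusted p was 0.0856 under quantile normalisation and 0.0778 with array weights, in a range over alternatives of 3.35e-07 to 0.350. The lists of downstream carbon metabolism did not pass the set test. For starch metabolism, 23 of 65 genes were higher and 29 lower (adjusted p = 0.119). For sucrose metabolism and sugar transport, 33 of 109 were higher and 41 lower (adjusted p = 0.370), with a median and mean above 0 and a test direction below it. For glycolysis and the TCA cycle, 39 of 140 were higher and 59 lower (adjusted p = 0.182). By over-representation, the KEGG citrate cycle had 52 of 72 genes lower and 11 higher (median log2 fold change -0.26, 1-sided Fisher's exact test, adjusted p = 5.21e-10). KEGG pyruvate metabolism had 62 of 117 lower and 27 higher (median -0.24, adjusted p = 4.77e-05). The KEGG term carbon metabolism had 153 of 346 lower and 114 higher (Fisher's exact test, adjusted p = 1.61e-05). Glyoxylate and dicarboxylate metabolism had 39 of 85 lower and 37 higher (Fisher's exact test, adjusted p = 0.0339). Over-represented among higher genes were KEGG starch and sucrose metabolism, with 88 of 216 higher and 67 lower (adjusted p = 0.0143), and fructose and mannose metabolism, with 44 of 100 higher and 24 lower (adjusted p = 0.0424). In the list for glycolysis and the TCA cycle, a pair of pyruvate kinase genes had the smallest adjusted p: GLYMA_16G173100 fell from 71.7 ± 1.95 to 12.9 ± 0.671 CPM and GLYMA_09G126300 from 105 ± 3.65 to 26.4 ± 0.892 CPM. For nitrogen assimilation, 15 of 33 were higher and 12 lower (adjusted p = 0.914), and for chlorophyll breakdown and senescence, 5 of 20 were higher and 7 lower (adjusted p = 0.227).

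Jasmonate and ethylene genes fell. Of 118 genes for jasmonate, a wounding and stress hormone, 65 were lower in MSN and 24 higher, also when adjusted over the list alone (median log2 fold change -0.32, set test adjusted p = 9.69e-11). Among the 32 lists it was the only list past the threshold with an estimated correlation (adjusted p = 0.0440). Examples chosen after their values were seen were GLYMA_15G179600, annotated to the regulation of jasmonate signalling, which fell from 424 ± 15.7 to 131 ± 1.12 CPM, and GLYMA_14G223200, a CoA ligase gene annotated to jasmonate synthesis, which fell from 478 ± 21.9 to 153 ± 2.83 CPM. GLYMA_13G347700, an oxylipin synthesis gene chosen in the same way, fell from 408 ± 12.6 to 348 ± 22.1 CPM. For ethylene and AP2/ERF factors, 19 of 27 genes were lower and 2 higher (set test adjusted p = 4.62e-05; adjusted p = 0.172 with an estimated correlation). Its abundant members, chosen in the same way, included ACC oxidase genes, whose product makes ethylene: GLYMA_14G049500 fell from 609 to 259 CPM (log2 fold change -1.23, SE 0.04) and GLYMA_02G268000 from 885 to 557 CPM (log2 fold change -0.67, SE 0.04). In the wider list of ethylene response terms, 56 of 100 genes were lower and 11 higher (set test adjusted p = 5.33e-07; adjusted p = 0.0255 with an estimated correlation). GLYMA_16G012600, a transcription factor gene of ethylene signalling, fell from 363 ± 24.4 to 119 ± 3.58 CPM, and GLYMA_07G044300, another, from 353 ± 9.39 to 286 ± 9.68 CPM. Genes annotated to the negative regulation of ethylene signalling fell too, with 13 of 21 lower and 1 higher (1-sided Fisher's exact test, adjusted p = 0.0388). The counts of falling genes therefore do not give the direction of signalling.

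**Figure D2:**
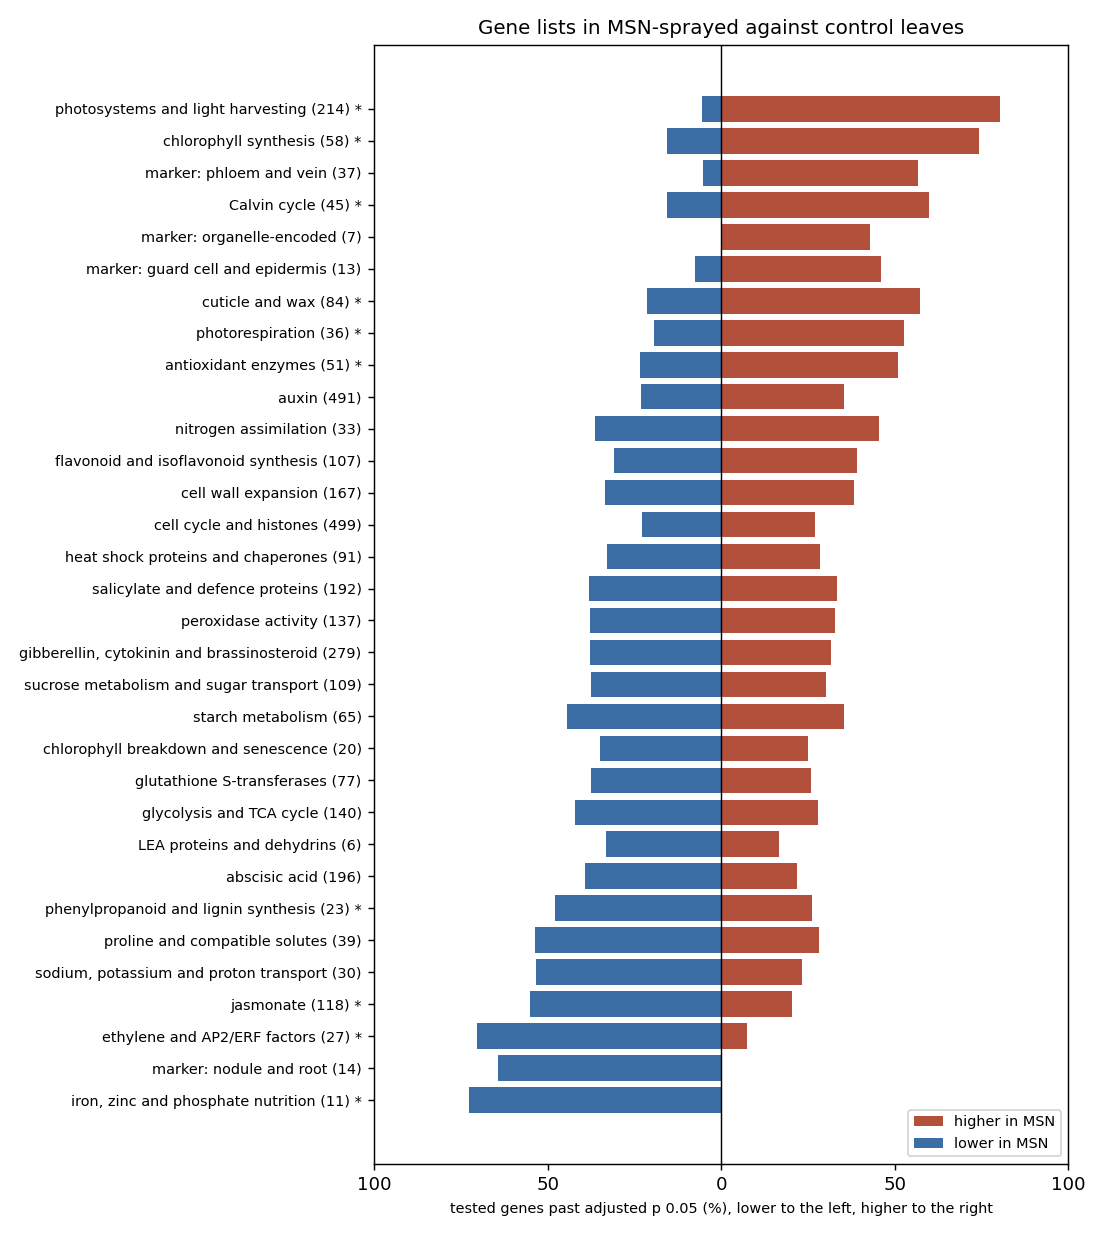
Percent of the tested genes of each of 32 lists that were higher (right) or lower (left) in MSN than in control leaves at an adjusted p under 0.05, with the number tested in parentheses and an asterisk where the list passed the set test at a preset correlation. Photosystems and light harvesting (172 of 214 higher) stand at the top, and iron, zinc and phosphate nutrition (8 of 11 lower) at the bottom.

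The other hormone lists held many called genes that went both ways, and none of them passed the set test. Of 491 auxin genes, 173 were higher and 113 lower (adjusted p = 0.620). GLYMA_15G022300, an auxin conjugate hydrolase gene, fell from 216 ± 4.81 to 84.3 ± 4.62 CPM, and GLYMA_08G004100, an auxin response gene, from 110 ± 1.84 to 44.3 ± 1.98 CPM. Of 279 gibberellin, cytokinin and brassinosteroid genes, 88 were higher and 106 lower (adjusted p = 0.220). GLYMA_03G148300, annotated to gibberellin binding, fell from 242 ± 5.40 to 80.9 ± 1.39 CPM, and GLYMA_13G360600, annotated as a negative regulator of cytokinin signalling, from 70.1 ± 2.44 to 18.8 ± 0.686 CPM. Of 196 abscisic acid genes, 43 were higher and 77 lower (adjusted p = 0.377). GLYMA_10G139500, a peptidyl-prolyl isomerase gene annotated to abscisic acid and salt response, rose from 34.8 ± 1.77 to 129 ± 5.90 CPM, and GLYMA_17G079000 fell from 26.8 ± 0.571 to 5.48 ± 0.155 CPM. Of 192 salicylate and defence genes, 64 were higher and 73 lower (adjusted p = 0.220; median above 0, mean and test direction below it). The chitinase genes GLYMA_09G038500 and GLYMA_19G245400 fell from 44.9 ± 3.90 to 7.00 ± 0.299 CPM and from 53.9 ± 0.549 to 14.5 ± 0.960 CPM. Defence response terms had 215 of 695 genes higher and 208 lower (adjusted p = 0.680; median above 0, mean and test direction below it). By over-representation among lower genes, the single terms abscisic acid-activated signalling (51 of 116 lower, 26 higher, adjusted p = 0.0283), plant-type hypersensitive response (17 of 22 lower, 3 higher, adjusted p = 0.000465), regulation of defence response (23 of 35 lower, 8 higher, adjusted p = 0.000950) and plant-pathogen interaction (99 of 241 lower, 57 higher, adjusted p = 0.0119) passed. Among higher genes, auxin transport did (11 of 16 higher, 2 lower, adjusted p = 0.0309).

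Among stress protection lists, antioxidant enzymes passed the set test, with 26 of 51 genes higher and 12 lower (adjusted p = 0.00580; adjusted p = 0.392 with an estimated correlation; 27 and 12 adjusted over the list alone). A peroxiredoxin gene, GLYMA_02G198400, rose from 246 ± 15.3 to 477 ± 1.83 CPM, and the catalase gene CAT4 (GLYMA_04G017500) from 430 ± 16.8 to 472 ± 6.80 CPM; both were chosen after their values were seen, and CAT4 turned to -0.047 on the log2 scale under quantile normalisation. Genes annotated with peroxidase activity had 45 of 137 higher and 52 lower (adjusted p = 0.239). In that list GLYMA_18G211000 fell from 37.5 ± 1.54 to 4.28 ± 0.327 CPM, and GLYMA_08G136200, whose other annotation is calcium-dependent phospholipid binding as in annexins, from 441 ± 11.9 to 143 ± 3.02 CPM. Glutathione S-transferases (20 of 77 higher, 29 lower, adjusted p = 0.237), heat shock proteins and chaperones (26 of 91 higher, 30 lower, adjusted p = 0.898; mean above 0, median and test direction below it), LEA proteins and dehydrins (1 of 6 higher, 2 lower, adjusted p = 0.403) and proline and compatible solutes (11 of 39 higher, 21 lower, adjusted p = 0.0926) did not pass. Sodium, potassium and proton transport had 7 of 30 genes higher and 16 lower (adjusted p = 0.0532), with 0.0494 under DESeq2 and under quantile normalisation and a range over the alternatives other than fry of 0.0494 to 0.204. Salt, osmotic and water deficit response terms had 51 of 142 higher and 37 lower (adjusted p = 0.974), and sodium, potassium and proton carrier terms 26 of 92 higher and 24 lower (adjusted p = 0.956). By over-representation, the single term response to salt stress had 37 of 79 genes higher and 20 lower (adjusted p = 0.0269), and potassium ion transport had 33 of 60 lower and 11 higher (adjusted p = 0.00274). By Fisher's exact test, unfolded protein binding (101 of 251 higher, 61 lower, adjusted p = 0.0113) and chaperone-mediated protein folding (21 of 33 higher, 5 lower, adjusted p = 0.00259) passed among higher genes. Hsp70 protein binding passed among lower genes (15 of 26 lower, 1 higher, adjusted p = 0.0466).

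Leaf surface genes rose and a small nutrition list fell. For cuticle and wax, the lipid coat of the epidermis, 48 of 84 genes were higher and 18 lower, with a median log2 fold change of 0.74 (set test adjusted p = 6.15e-06; adjusted p = 0.0996 with an estimated correlation; 48 and 18 adjusted over the list alone). Beside them, guard cell and epidermis markers had 6 of 13 genes higher and 1 lower, and phloem and vein markers 21 of 37 higher and 2 lower. The 3 called cuticle and wax members of highest abundance, chosen after their values were seen, went both ways. GLYMA_09G123800, a monooxygenase gene of the cutin, suberin and wax pathway, fell from 275 ± 8.14 to 173 ± 7.42 CPM. GLYMA_04G057800, a very-long-chain ketoacyl-CoA synthase gene, rose from 99.0 ± 4.20 to 161 ± 2.36 CPM, and GLYMA_10G010800, annotated to wax and cutin synthesis, from 76.1 ± 3.39 to 170 ± 2.66 CPM. For phenylpropanoid and lignin synthesis, 11 of 23 genes were lower and 6 higher (set test adjusted p = 4.47e-06; 12 and 6 adjusted over the list alone), and this list's adjusted p was 0.0652 with an estimated correlation, 0.0639 under quantile normalisation, 0.0660 with array weights and 0.0551 and 0.0674 on FPKM with pseudocounts of 1 and 0.1, with a lowest value over alternatives of 1.23e-06. Its phenylalanine ammonia-lyase genes, the entry step of the pathway, went both ways: GLYMA_10G058200 rose by 0.56 (SE 0.03) and GLYMA_13G145000 fell by 0.61 (SE 0.04) on the log2 scale, both chosen after their values were seen. For iron, zinc and phosphate nutrition, 8 of 11 genes were lower and 0 higher (set test adjusted p = 0.0342; adjusted p = 0.221 with an estimated correlation). GLYMA_13G001500, annotated to iron-nicotianamine transport and chosen in the same way, fell from 188 ± 8.54 to 102 ± 5.42 CPM. Iron homeostasis terms had 34 of 81 higher and 21 lower (adjusted p = 0.235), and phosphate transport terms 13 of 49 higher and 19 lower (adjusted p = 0.814). Nitrate terms had 9 of 28 higher and 11 lower (adjusted p = 0.814).

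Growth lists went both ways. Of 499 cell cycle and histone genes, 135 were higher and 114 lower (adjusted p = 0.567). By at least 1 on the log2 scale, 50 of them rose and 11 fell. Over-represented among higher genes were microtubule motor activity, with 59 of 132 higher and 15 lower (1-sided Fisher's exact test, adjusted p = 0.00816), and the kinesin complex. The kinesin complex had 50 of 116 higher and 15 lower (Fisher's exact test, adjusted p = 0.0387). GLYMA_06G090500, annotated as a structural constituent of microtubules, fell from 226 ± 9.49 to 109 ± 2.32 CPM, and the mitotic spindle gene GLYMA_11G213500 from 12.4 ± 0.465 to 0.677 ± 0.213 CPM. Of 167 cell wall expansion genes, 64 were higher and 56 lower (adjusted p = 0.887). GLYMA_12G192100, a cellulose synthase family gene, fell from 200 ± 5.23 to 64.2 ± 0.895 CPM, and GLYMA_02G015600, a polygalacturonase gene, from 127 ± 2.47 to 23.1 ± 2.65 CPM. Flavonoid and isoflavonoid synthesis had 42 of 107 higher and 33 lower (adjusted p = 0.885), and xyloglucan transferase terms 13 of 47 higher and 14 lower (adjusted p = 0.0593; median above 0, mean and test direction below it), passing in 3 of 19 alternatives other than fry. Water channel terms had 22 of 43 higher and 12 lower (adjusted p = 0.882; median and mean above 0, test direction below it), sugar transporter terms 20 of 93 higher and 37 lower (adjusted p = 0.0551, passing in 6 of 19), and heat response and protein folding terms 125 of 316 higher and 81 lower (adjusted p = 0.0979). For all 32 lists fixed beforehand, counts adjusted over the list alone differed from those over all genes by at most 4 genes in either direction.

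Markers of other organs and cell types moved in part. Phloem and vein markers had 21 of 37 genes higher and 2 lower, with a median log2 fold change of 0.85 (adjusted p = 0.0520), and passed in 11 of 19 alternatives other than fry. Their most abundant members were GLYMA_20G218600, at 75.5 ± 3.49 CPM in control and 103 ± 4.16 CPM in MSN, and GLYMA_06G044600, at 70.7 ± 2.03 and 45.1 ± 1.33 CPM. Nodule and root markers had 9 of 14 genes lower and 0 higher (adjusted p = 0.122), and passed in 5 of 19 such alternatives; the most abundant were GLYMA_12G210400, at 109 ± 0.499 and 94.9 ± 1.26 CPM, and GLYMA_14G007300, at 71.7 ± 1.85 and 73.6 ± 2.42 CPM. Guard cell and epidermis markers had 6 of 13 higher and 1 lower (adjusted p = 0.182; median and test direction above 0, mean below it) and passed in 3 of 19, with GLYMA_08G345100, an epidermal patterning factor of stomatal development, at 47.4 ± 3.51 and 92.7 ± 2.66 CPM and GLYMA_13G342900 at 41.5 ± 0.750 and 42.4 ± 1.30 CPM. Organelle-encoded gene names had 3 of 7 higher and 0 lower (adjusted p = 0.370). The table places petA and rpl33, plastid genes by name, on chromosome 12, at 61.3 ± 0.335 and 76.7 ± 5.26 CPM for petA and 2.99 ± 0.818 and 4.35 ± 0.220 CPM for rpl33; rpl33 (GLYMA_12G232300) had an adjusted p of 0.0829 without control replicate 3, against 0.0142 with all libraries. Storage protein terms had 14 of 48 higher and 12 lower (adjusted p = 0.110).

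The largest falls named by the rule, which takes only genes with a description, were genes present in every control library and at a count of 0 in all 3 MSN libraries. Fitted folds rank genes at 0 first, and GLYMA_19G011300, a described gene with 3995 counts in control and 4 in MSN, was not named. Of genes without a description, GLYMA_04G180400 (chromosome 4, 44623575 to 44628878) fell from 105715 to 15 counts. GLYMA_16G070000, also without one, fell from 8547 to 0, at least 704-fold. These examples were chosen after their values were seen. GLYMA_19G085200, a membrane transporter gene on chromosome 19 at 30438449 to 30443027, stood at 123 ± 3.30 CPM in control and was at least 2013-fold lower in MSN. GLYMA_19G069300, annotated to protein kinase activity and polysaccharide binding (21902720 to 21908889), stood at 31.4 ± 1.60 CPM and was at least 515-fold lower. GLYMA_06G198600 (chromosome 6, 18059627 to 18063976), annotated only to protein binding, was at least 394-fold lower, and GLYMA_04G180300 (chromosome 4, 44611968 to 44613556), annotated to protein kinase activity, at least 251-fold. GLYMA_07G156900 (chromosome 7, 19271212 to 19273538), annotated to proton transport, was at least 199-fold lower, and its span overlaps that of GLYMA_07G157000 on the same strand. GLYMA_18G166600 (chromosome 18, 38955092 to 38962893), annotated to GPI anchor attachment, was at least 163-fold lower. The adjusted p of the 6 falls named by the rule lay between 6.40e-20 and 3.57e-14 (edgeR).

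The largest rises named by the rule, which takes only genes with a description, were of genes with few or no counts in control. GLYMA_16G174300, which has no description and was chosen after its values were seen, had 23 counts in control and 8960 in MSN, a 395-fold rise. GLYMA_11G185100 (chromosome 11, 25346550 to 25351646), a fatty acyl-CoA reductase gene of wax and suberin synthesis, had no counts in control and 1.59 ± 0.338 CPM in MSN, at least 26.5-fold higher. GLYMA_14G169900 (chromosome 14, 42018793 to 42024034), annotated to folic acid binding, reached 1.41 ± 0.323 CPM, at least 23.4-fold higher. GLYMA_18G236700 (chromosome 18, 52558809 to 52562720), a polygalacturonase gene, rose 174-fold from 0.159 ± 0.113 to 27.8 ± 0.912 CPM. GLYMA_11G185100 and GLYMA_14G169900 were ranked above it by fitted folds against a group at 0, while their lower bounds lie under 174-fold. GLYMA_14G064500 (chromosome 14, 5283217 to 5291502), a serine endopeptidase gene, had 9 counts in control and 1517 in MSN, a ratio with a counting interval of 52.8 to 1590. GLYMA_19G250400 (chromosome 19, 49639900 to 49642287), annotated to ester hydrolysis, had 11 and 870 counts, with an interval of 24.9 to 360. GLYMA_02G028600 (chromosome 2, 2604249 to 2605917), a metalloendopeptidase gene whose span overlaps that of GLYMA_02G028700, had 12.6 and 11.6 CPM in MSN replicates 1 and 2 and 0.251 CPM in MSN replicate 3, against 0.0501 ± 0.0172 CPM in control, a ratio with a counting interval of 56.5 to 1703. Its log2 fold change was 7.29 over all libraries and 7.86 without MSN replicate 3, and its adjusted p was 0.0664 under quantile normalisation, 0.0668 with array weights, and 0.111 and 0.127 on FPKM with pseudocounts of 1 and 5, from a low over alternatives of 1.48e-13.

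Photosynthesis, surface lipid and hormone signalling terms were over-represented among changed genes. Of 2033 terms, 121 were over-represented among higher genes and 204 among lower genes. Higher genes made up 184 of 253 genes of the chloroplast thylakoid membrane (adjusted p = 6.31e-41), 92 of 109 of photosystem II (adjusted p = 6.80e-29) and 21 of 27 of cutin, suberin and wax synthesis (adjusted p = 3.06e-05), against 30.2% of the background. Lower genes made up 30 of 37 genes for the regulation of jasmonate signalling (adjusted p = 9.53e-08) and 47 of 72 of the ethylene-activated signalling pathway (adjusted p = 3.76e-07), against 31.1% of the background. Fisher's exact test treats genes as independent, which co-regulated genes are not.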

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

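The tests chosen only after the data were seen were those on counts divided by 4, against a fold of 1.5, on log2(FPKM + 1) and with the lists as first written. The gene counts stayed within 1.5 times their values under every alternative run except the fold criteria. The number past the threshold was 23256 and ranged from 17157 (mean of at least 5 CPM, which tests fewer genes) to 23786 (array weights). Of the genes past the threshold, 22825 were shared with DESeq2's Wald test, 21854 with quantile normalisation and 22183 with counts divided by 4. Leaving out each library in turn gave 21645 to 22452 genes, with 22452 without control replicate 2, the library with the most ribosomal RNA. A log2 fold change of at least 1 left 6384 genes (3636 higher, 2748 lower), and a test against a fold of 1.5 left 7524 (4180 higher, 3344 lower). Of the genes called, 49.5% were higher with DESeq2 size factors and 49.9% under quantile normalisation. These scalings, like TMM, centre the fold changes: the median log2 fold change over genes was 0.0025, -0.0088 and 0.0055, in that order. A near even split is thus largely built in, and it cannot show that rises and falls balance.

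With the replicate number as a block, 22741 genes passed and 11 lists passed the set test. Same-numbered libraries deviated together by -0.00258 to 0.0104, and 3 of the 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples.

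Of 32 lists, 10 passed the set test; 1 passed with an estimated correlation and 28 with fry, which asks another question, whether a list's genes move on balance and not whether they differ from other genes. The other alternatives gave 10 to 13 lists. No list turned direction where it passed in the main test or in the alternative. Turns of lists that passed in neither were not counted. Salt, osmotic and water deficit response terms, which passed in neither, were up with camera and down with fry. Apart from fry, starch metabolism passed with DESeq2 alone (adjusted p = 0.0432, range 0.0432 to 0.515), sugar transporter terms in 6 of 19 alternatives (range 0.0226 to 0.350) and xyloglucan transferase terms in 3 (range 0.000932 to 0.792). The fold threshold and the test against a fold of 1.5 have no set test of their own. Over the 30 genes named by the rule and the alternatives, 520 of the recomputed fold changes kept direction and side of the threshold and 4 lost the call, all for GLYMA_02G028600. Among the other named genes 798 fold changes kept both, 21 lost the call (16 against a fold of 1.5, 3 under quantile normalisation, 1 without MSN replicate 2, 1 without control replicate 3), 1 gained it and 1 reversed, CAT4 (GLYMA_04G017500) at -0.047 under quantile normalisation; the cause was not tested. Depth limited genes of low counts in the simulation with 200 changed genes. With counts in steps of 4, simulated 1.5-fold changes were found in 16 of 26 genes under a mean of 1000 counts and in 24 of 24 above it. These shares were not simulated at the number of genes called in the data.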

Other observations

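The tests of explanations given here were chosen only after the results they bear on were seen. Several groups of genes not described so far were over-represented among lower or higher genes (1-sided Fisher's exact test, adjusted over 2033 terms, against 31.1% lower and 30.2% higher in the background). Lower genes in MSN made up 82 of 127 translation initiation factor genes (adjusted p = 1.80e-11), 217 of 461 genes of intracellular protein transport (adjusted p = 4.49e-10), 135 of 260 genes of protein processing in the endoplasmic reticulum (adjusted p = 7.74e-10) and 24 of 27 genes annotated as protein tags, the class of ubiquitin (adjusted p = 1.16e-07). In the same order, 14, 60, 37 and 1 of their genes were higher. Their shifts were small, with median log2 fold changes of -0.24, -0.16, -0.17 and -0.31. Shifts of this size depend on the scaling, which centres fold changes near 0. Secondary cell wall synthesis stood out by size, with 53 of 75 genes lower, 5 higher and a median of -1.02 (adjusted p = 7.74e-10), and response to wounding had 32 of 46 genes lower and 8 higher with a median of -0.59 (adjusted p = 8.77e-06). Of the secondary cell wall genes, GLYMA_05G161900, GLYMA_08G119500, GLYMA_12G068900 and GLYMA_12G069400 carry the same annotation. They are among the genes all but missing from MSN leaves that are described below.

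Among higher genes, all of 10 genes of plastid transcription were higher (median 0.93, adjusted p = 0.000282), as were 14 of 17 genes of sucrose synthesis (median 0.78, adjusted p = 0.000535), 15 of 18 of phloem development (median 1.31, adjusted p = 0.000229) and 49 of 100 of the nucleosome (median 0.28, adjusted p = 0.00223). Lower genes numbered 0, 1, 0 and 13 in these groups. Cytosolic ribosome genes had 69 of 401 higher and 152 lower (set test adjusted p = 0.814), and circadian rhythm terms 30 of 123 higher and 49 lower (set test adjusted p = 0.180).

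A set of genes was present in control leaves and all but missing from MSN leaves. With at least 300 counts over the control libraries and at most 1% of that in MSN, there were 41 such genes, 27 of them with no count in any MSN library; the opposite pattern held for 6 genes. A candidate explanation is that the plants of the 2 groups differ in genotype at these genes, although the labels give 1 genotype for all: 12 of the 41 lay within 1 Mb of another, against a median of 6 in 10000 expression-matched random sets (permutation p = 0.0290). The 12 include GLYMA_07G156900 and GLYMA_07G157000, whose spans overlap on the same strand, so not all of them are independent. Draws of 41 from the 123 genes that fell only to 1 to 10% gave a median of 7 (permutation p = 0.0802), which does not pass the threshold, so genotype and control by the treatment cannot be told apart here. Among genes with at least 3000 control counts, 8 lay below 0.400%, 13 between 0.400 and 4.00% and 581 between 4.00 and 40.0%. The steep drop from 581 to 13 did not continue from 13 to 8. With so few genes in a lowest range that reaches to 0, it stays open whether they are only the far end of a continuous range of falls.

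The share of tested genes past the threshold, 59.3%, was weighed too. With the steps of 4 in the counts as a possible cause, 22694 of 34724 tested genes passed after division by 4. The fit estimates the spread from the replicates with or without the division, so this is a weak test of that cause. The median spread between libraries beyond counting noise was 1.91% of the mean in control and 1.77% in MSN in genes above 5000 counts, and negative in genes of fewer counts (-16.1 to -0.107%), where the variance averaged 4.31 to 7.38 times the mean. It stays open whether the 3 libraries of a group share plants or handling, in which case their spread could understate that between plants. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of 10, the real split, gave as many genes (23256, with 11594 higher and 11662 lower), and the highest of the others gave 0. Each of the other splits mixes control and MSN libraries, so the difference between groups enters its spread and the 0 decides nothing. For the set test, 2 of 10 splits gave as many lists as the real one, which gave 10, and the highest of the others gave 10. The other splits, each with 0 genes past the threshold, still passed 2 to 10 lists. The sides of each hold unequal numbers of control and MSN libraries, so part of the group difference stays in the contrast. The list counts of these splits therefore decide nothing either.

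For the rise of photosystem and light harvesting genes, a trend of fold change with gene length (Spearman rho = -0.0499 across genes, which are not independent) was removed, and the list's median log2 fold change went from 0.60 to 0.55 (bootstrap SE 0.03), so length is not the whole cause. Harvest at another time of day could raise the same genes: the size of change of circadian rhythm genes lay at percentile 25.7 of 10000 expression-matched lists, which decides nothing. Younger or faster growing leaves in MSN could do so as well. Cytosolic ribosome genes had a median of -0.070 (95% interval from a bootstrap SE over genes, -0.0995 to -0.0405) with members going both ways. Over-represented among lower genes were large subunit genes (98 of 246 lower, 37 higher), KEGG ribosome biogenesis (61 of 113 lower, 10 higher) and translation initiation factors. Nucleosome and kinesin complex genes were over-represented among higher genes. As these groups go opposite ways, growth too stays open as a cause. An effect of the particles on photosynthesis genes is the explanation that the design names, and it remains a hypothesis beside these. A difference between the groups in genotype, plants, handling or what the control leaves were sprayed with would bear on these genes too. It would bear on every other comparison of the groups given here, and it cannot be told apart from the treatment.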
